A study of Mus musculus with 22 samples.

How the data were processed

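The 12 RNA-seq libraries came from E14 mouse embryonic stem cells after 1 day with 2 µM retinoic acid: 3 WT, 3 E1-KO, 3 E2-KO and 3 D-KO, grouped by the genotype in the labels. D-KO is not spelled out there and is read as the deletion of both elements. The 4C and ChIP samples of the series were not analysed here. Total RNA was extracted with Trizol, per the labels' protocols. Each library has a table of read counts per gene as deposited by the authors, who aligned to mm10 with HISAT2 2.1.0, counted with HTSeq 0.9.1 and list DESeq2 1.18.1, per the submitters' processing notes. The annotation and the strand setting of the counting are not given in the sources used here. Reads counted on genes lying inside exons of the opposite strand were therefore examined. The expected count was the count per base of the gene on the opposite strand, times the length of the gene inside. Over 71 such genes the median ratio of observed to expected counts was 1.14 (quartiles 0.290 and 2.09). Reads of a gene and its antisense partner are thus not told apart here.

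The counts are raw whole numbers per gene symbol, with 52535 symbols in each of the 12 tables. HTSeq's lines for reads without a gene stayed out of library sizes and tests; reads with no feature were 1.11 to 1.20 times the counted reads. Totals of 9101547 to 13007735 counts per library put 3 counts over a group, the floor used for genes with 0 counts, at 0.0949 to 0.102 CPM. Folds against such groups are given as bounds, and ratios with 1 to 3 counts with exact 95% intervals, which cover counting error only. Positions and gene types come from the GENCODE M21 names and RefSeq GRCm38.p6 tables, matched by symbol (48108 and 35103 of 52535 symbols).

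Differences were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr on genotype (16765), libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 12 libraries with a mean per genotype and no covariate (common dispersion 0.0265). Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, with no fold minimum. The 7 contrasts were each KO genotype against WT, the 3 pairs of KO genotypes, and the interaction D-KO - E1-KO - E2-KO + WT. All adjusted p-values of single genes are from edgeR unless limma 3.58.1 or DESeq2 1.42.0 is named. Errors of log2 fold changes are standard errors of the unshrunken coefficients, from the model's information and the quasi-dispersion, and those of TMM-normalised CPM are SDs over 3 libraries. Estimates lean on a spread shared by all genotypes, and the median tagwise dispersion was 0.0935 among WT and 0.00660 among KO libraries. The shared spread thus understates that of WT and overstates that of the KO genotypes. Standard errors and p-values against WT are therefore likely too small, and those between KO genotypes too large.

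Before the data were examined, 26 gene lists were fixed from general knowledge: the HoxB cluster and its non-coding RNAs, genes flanking it, HoxA, HoxC and HoxD, retinoic acid response, naive and general pluripotency, formative and primed epiblast, primitive endoderm, early neural, primitive streak and mesoderm, trophectoderm, 2-cell-like, fibroblast, germline, proliferation, p53 targets, amino acid and ER stress, Nodal, FGF and ERK, and Wnt response, imprinted, Y-linked and mitochondrially encoded genes. Tfap2c, Sesn2, Tdgf1 and Ascl2 stand in 2 lists each, and stem cells express many members of the other lineage lists too. The 24 lists with at least 3 tested members were tested with camera (inter-gene correlation 0.01), adjusted over the lists of a comparison; camera with an estimated correlation and fry were alternatives. Of 37 list calls against WT, 27 held with the estimated correlation. Calls were also counted with p-values adjusted over a list alone. The rule for named genes took, for each comparison with WT, all HoxB members, the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 1 and all 3 libraries of one genotype above the other's, leaving out symbols of predicted loci, and up to 3 members of each list with the smallest adjusted p. For the other contrasts it took the HoxB members and the 5 largest rises and falls, for the interaction without the rule on separated libraries. Some genes that the rule picked are not reported here by name, and all counts and tests include them.

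Overlaps between comparisons with WT were set beside the product of list sizes and beside 20 simulations of unchanged groups. In each simulation all 12 libraries were drawn anew, gene by gene, and the 3 comparisons shared the drawn WT libraries. Dispersions of WT and KO libraries were kept apart, but trends across genes within a library were not reproduced. The edgeR step was tested on simulated counts of 16414 genes: 70% of changes of 1 and 98% of changes of 2 on the log2 scale were recovered for D-KO against WT with 9 unchanged genes called, 73% and 99% for D-KO against E1-KO with 14, and 38% and 91% for the interaction with 15. On data with the primitive endoderm list shifted, camera called that list and 0 of 23 others, at an adjusted p below 0.05. These simulated counts had the same dispersion in all genotypes, without the larger spread among WT libraries, so the rates need not hold for the real data. Alternatives were RLE, upper-quartile and total scaling, other filters, DESeq2, limma-voom, only the 6 libraries compared, a replicate block, a limma model additive in CPM, a threshold of 0.01 and each of the 12 libraries left out. Chosen after seeing the data were removal of GC content and length trends (known for 97.8% of tested genes), sample quality weights in limma-voom, the 9 KO libraries alone, and a fit without WT replicates 1 and 3, the WT libraries with the steepest GC trends. That fit keeps 1 WT library, whose spread is assumed to be that of the KO groups. Chromosome windows of 10 Mb with at least 20 expressed genes were compared by their median log2 fold change, uncorrected for the size of the shared fall and GC-corrected for the number of windows.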

Results

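RNA was sequenced from E14 cells, a mouse embryonic stem cell line, after LIF and both kinase inhibitors that hold such cells in the naive state had been removed and 2 µM retinoic acid had been given for 1 day. Retinoic acid is the vitamin A derivative that switches on Hox genes in these cells. The 12 libraries fell into 4 genotypes with 3 libraries each: unedited cells (WT), cells without the element E1 (E1-KO), cells without the element E2 (E2-KO) and cells labelled D-KO, read here as lacking both elements. The series concerns how enhancers, E1 and E2, act on the HoxB genes and on early differentiation. The libraries held 9101547 to 13007735 reads counted to genes, with WT at 9507298 to 13007735, E1-KO at 9562262 to 10342463, E2-KO at 9101547 to 10433253 and D-KO at 10137742 to 10593418. The series calls the libraries of a genotype biological replicates and does not say whether they came from separate cultures or clones. P-values therefore measure only the spread between these samples. The WT libraries lay much farther apart than those of the other genotypes. Their pairs differed by a chi-square of 44.7 to 88.5 per gene over 14006 genes. This compares with 2.25 to 4.23 for pairs within a KO genotype. Each pair differed by more than counting error alone. Mitochondrial transcripts took 3.50%, 1.94% and 5.88% of the counts of WT replicates 1, 2 and 3, 1.36% to 1.48% in E1-KO, 1.63% to 1.81% in E2-KO and 2.53% to 2.69% in D-KO. The Spearman correlation, across genes, of a library's relative expression with GC content was -0.66, 0.20 and -0.49 in WT replicates 1, 2 and 3, 0.30 to 0.42 in E1-KO, 0.37 to 0.52 in E2-KO and -0.12 to -0.03 in D-KO.

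The gene counts do not cover the deleted elements, whose positions are not given in the sources used here, so the HoxB genes are the nearest check of the genotypes. The HoxB cluster encodes homeodomain transcription factors that pattern the hindbrain and trunk, and lies on chromosome 11 (GRCm38) from Hoxb13 (96194316 to 96196610) to Hoxb1 (96365746 to 96368254), with Hoxb1 at the end that retinoic acid switches on first. Of its 10 genes, 9 fell in each KO genotype against WT, the exception being Hoxb13, which was low everywhere (1.94 ± 0.944 CPM in WT, SD, n = 3). The same 9 of 10 were called when p-values were adjusted over the list alone in E1-KO and E2-KO, and 10 of 10 in D-KO. Hoxb1 stood at 22.9 ± 7.50 CPM in WT, 0.291 ± 0.109 in E1-KO, 0.838 ± 0.450 in E2-KO and 0.528 ± 0.306 in D-KO. Hoxb4 stood at 29.1 ± 10.8 CPM in WT, 1.43 ± 0.546 in E1-KO, 3.92 ± 0.417 in E2-KO and 0.201 ± 0.176 in D-KO. Hoxb5 and Hoxb6 had 374 and 266 counts in the WT libraries together and 0 in the D-KO libraries, where 3 counts would correspond to 0.0998 CPM. Against that floor over the group they were at least 119-fold and 84.3-fold lower than in WT. Hoxb9, nearer to the other end of the cluster, kept more of its expression, with 15.4 ± 4.49 CPM in WT, 5.07 ± 0.462 in E1-KO, 3.29 ± 0.603 in E2-KO and 1.88 ± 0.820 in D-KO. Such floors cover counting error only.

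**Figure D1:**
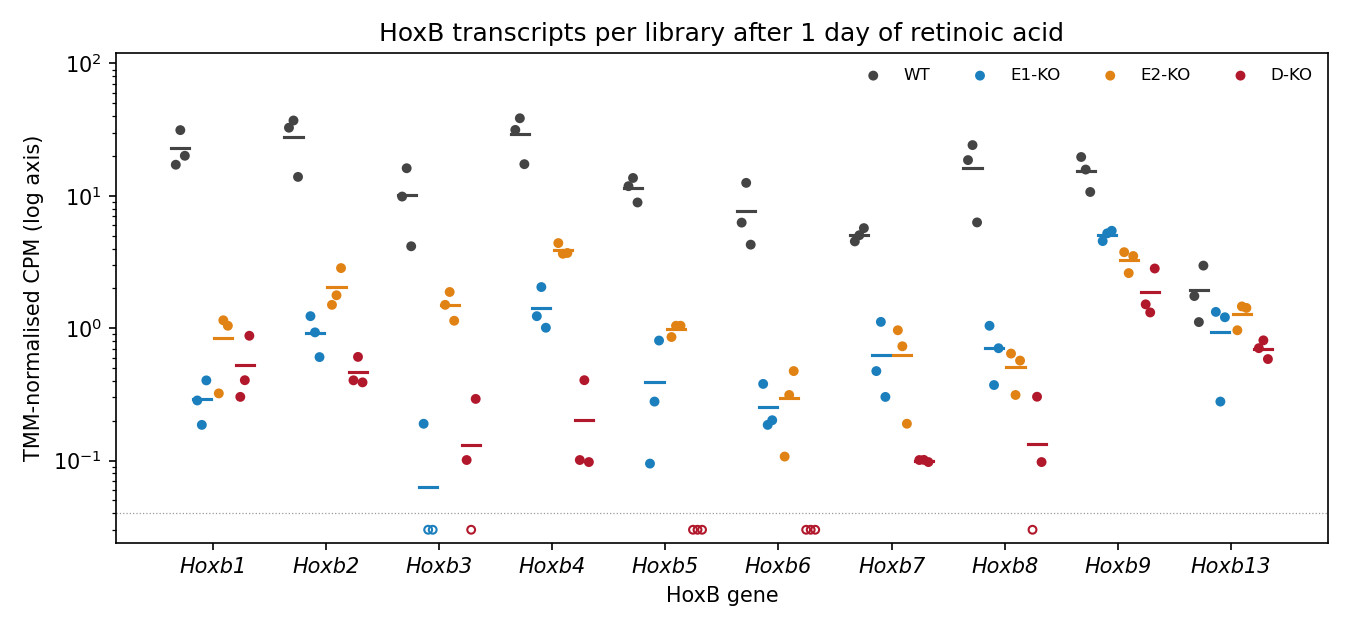
TMM-normalised CPM (log axis) of the 10 HoxB genes in each of the 12 libraries; each point is a library, bars are means of 3 libraries, and open points below the dotted line are libraries with 0 counts. Hoxb5 and Hoxb6 had 0 counts in all D-KO libraries, and the WT means of Hoxb1 and Hoxb4 were 22.9 and 29.1 CPM.

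In E1-KO 9 HoxB genes were lower than in WT, with the largest falls in Hoxb1 (log2 fold change -6.26 ± 0.59 SE, adjusted p = 3.25e-07), Hoxb2 (-4.90 ± 0.43) and Hoxb3, which had 2 counts in E1-KO against 349 in WT (log2 ratio of totals -7.43, 95% counting interval -10.48 to -5.56). The list as a whole fell (median log2 fold change -4.69, camera adjusted p = 1.17e-15). Of the 11 tested genes of the HoxA cluster on chromosome 6, 8 fell, among them Hoxa7 (-2.27 ± 0.15), Hoxa5 (-2.01 ± 0.14) and Hoxa10 (-2.44 ± 0.27), and the list fell (median -2.01, adjusted p = 3.32e-10). Of the 24 tested retinoic acid response genes 14 fell and 2 rose. Stra6, the cell-surface receptor for retinol-binding protein, fell by 2.28. Tgm2, transglutaminase 2, rose by 2.06, and the list fell (median -1.03, adjusted p = 9.79e-07). Primitive endoderm genes fell in 14 of 21 cases and rose in 3, with Gata6, a transcription factor that specifies this lineage, at -2.12 ± 0.10 and the endocytic receptor Cubn at -4.58 ± 0.31 (list median -2.01, adjusted p = 2.65e-14). Of 12 formative and primed epiblast genes 8 fell and 1 rose (median -1.03, adjusted p = 9.49e-05), with Sox3 at -2.98 ± 0.37. Naive pluripotency genes went the other way: 10 of 18 rose and 1 fell (median 0.66, adjusted p = 5.60e-06), with Esrrb at 1.29 ± 0.10 and Klf4 at 1.24 ± 0.12. Zscan4d (-4.08 ± 0.24) and 12 more of the 14 tested 2-cell-like genes, which mark a rare totipotent-like state of stem cell cultures, fell (median -3.59, adjusted p = 3.28e-19). The Zscan4 genes are near-identical copies, so the split of reads among them is uncertain. Trophectoderm genes rose in 7 of 12 cases with none called lower (median 0.85, adjusted p = 0.00333), led by Tead4, at 19.8 CPM in WT and 50.6 in E1-KO. With trends in GC content and length removed the list no longer passed (median 0.45, adjusted p = 0.109).

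In the same comparison, 10 of 15 genes of the amino acid and ER stress response rose and 1 fell, with Trib3 at 1.37 ± 0.17 and Hspa5, an ER chaperone, lower at -0.65 ± 0.11. The list rose (median 0.69, adjusted p = 0.000449), but not with an estimated correlation between its genes (adjusted p = 0.0939). Of 9 Nodal pathway genes 5 fell and 1 rose, with Lefty1 at -2.99 ± 0.25 (median -0.48, adjusted p = 0.00135). Of 22 imprinted genes 8 fell and 4 rose, led by Grb10, a growth-restraining adaptor, at -3.74 ± 0.10 (433 ± 21.1 CPM in WT, 32.4 ± 0.931 in E1-KO). The list's fall (median -0.20, adjusted p = 0.00263) no longer passed without WT replicates 1 and 3 (median -0.05). Mitochondrially encoded genes fell in 11 of 12 cases (median -1.52, adjusted p = 9.60e-06; adjusted p = 0.219 with an estimated correlation), while the WT libraries themselves spanned 1.94% to 5.88% of counts. Among HoxB non-coding RNAs Hoxb3os and Hoxb5os fell and Mir196a-1 did not pass (list median -4.51, adjusted p = 0.00491; adjusted p = 0.0939 with an estimated correlation, and no longer past the threshold without WT replicate 2). Both overlap coding HoxB genes on the opposite strand, and their reads cannot be told apart from those of the genes. The 26 tested genes flanking HoxB did not move together (8 rose, 5 fell, median 0.12, adjusted p = 0.461). Nor did the lists for general pluripotency (5 rose, 4 fell), early neural (2 rose, 4 fell), primitive streak and mesoderm (3 rose, 1 fell), fibroblast (1 rose), germline (2 rose, 1 fell), proliferation (1 rose, 8 fell), p53 targets (6 rose, 3 fell), FGF and ERK response (4 rose, 2 fell) and Wnt response genes (1 fell) pass. Of the Y-linked genes 4 of 4 tested fell; Ddx3y and Eif2s3y had 0 counts in all KO libraries. The largest rises outside the lists were Egr4, an early growth response factor with 2 counts in WT (log2 ratio of totals 5.86, counting interval 3.98 to 8.93), Efhc2 (5.44 ± 0.33), Spint5, Loxl4 (4.79 ± 0.53), H2-Eb1, an MHC class II chain (4.64 ± 0.36), and Cyp2b23 (4.41 ± 0.15). Msx1, a homeobox gene, fell by 5.58. In all, 5739 of 16765 genes differed at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test, 2633 higher and 3106 lower, of which 2149 by at least 1 on the log2 scale. With the 6 libraries of both genotypes alone the count was 2552, without WT replicate 2 it was 8753, and with library totals as the only scaling 57.1% of the calls were rises instead of 45.9%.

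In E2-KO the same 9 HoxB genes were lower than in WT, with list median -3.28 (adjusted p = 7.35e-13) and log2 fold changes of -4.74 ± 0.41 for Hoxb1, -4.99 ± 0.64 for Hoxb8, -2.90 ± 0.30 for Hoxb4 and -2.22 ± 0.28 for Hoxb9. HoxA genes fell in 7 of 11 cases (median -1.04, adjusted p = 7.24e-06). Retinoic acid response genes fell in 11 and rose in 3 of 24 cases (median -0.59, adjusted p = 0.00238), a call that was lost with an estimated correlation (adjusted p = 0.168) and without WT replicate 2 (median -0.36). Primitive endoderm genes fell in 14 and rose in 3 of 21 cases (median -1.14, adjusted p = 0.000299), with Cubn at -2.48 ± 0.23 and Gata6 at -0.95 ± 0.10. Formative and primed epiblast genes fell in 7 of 12 cases and rose in 1 (median -0.52, adjusted p = 0.00542), the rise being Dnmt3b, a de novo DNA methyltransferase, at 0.54 ± 0.10. Naive pluripotency genes rose in 10 and fell in 2 of 18 cases (median 0.49, adjusted p = 0.000655), with Klf2 at 1.61 ± 0.20. All 14 tested 2-cell-like genes fell (median -3.51, adjusted p = 5.27e-20). Stress response genes rose in 12 and fell in 1 of 15 cases (median 0.91, adjusted p = 2.52e-07), with Atf3 at 2.06 ± 0.27 and Chac1 at 1.61 ± 0.22. Trophectoderm genes rose in 7 of 12 cases (median 0.93, adjusted p = 0.00610; median 0.43 and adjusted p = 0.186 with GC content and length trends removed). Imprinted genes fell in 8 and rose in 3 of 22 cases (median -0.25, adjusted p = 0.00542), with Grb10 at -3.05 ± 0.10, and 4 of 4 tested Y-linked genes fell. Mitochondrially encoded genes fell in 9 of 12 cases (median -1.15, adjusted p = 0.000714; adjusted p = 0.330 with an estimated correlation), a call also lost without WT replicates 1 and 3 (median -0.19). HoxB non-coding RNAs fell in 2 of 3 cases (median -3.20, adjusted p = 0.0113; adjusted p = 0.107 with an estimated correlation, and lost without WT replicate 2).

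The lists that did not pass in E2-KO were genes flanking HoxB (6 rose, 5 fell), general pluripotency (5 rose, 3 fell), early neural (1 rose, 3 fell), primitive streak and mesoderm (2 rose, 1 fell), fibroblast (1 rose), germline (2 rose, 1 fell), proliferation (1 rose, 6 fell), p53 targets (4 rose, 4 fell), Nodal signalling (2 rose, 4 fell), FGF and ERK response (4 rose) and Wnt response (2 fell). Nodal signalling passed without WT replicate 1, WT replicate 3 or D-KO replicate 3 (medians -0.27, 0.02 and -0.06), and general pluripotency without WT replicate 3 (median 0.15). Csmd3, a large membrane protein gene on chromosome 15, had 0 counts in WT and E1-KO and 603 counts in E2-KO, at least 216-fold higher than the WT floor. Egr4 (log2 ratio of totals 6.04, counting interval 4.16 to 9.11), Loxl4, Cyp2b23 (4.76 ± 0.15), Spint5 and H2-Eb1 (3.96 ± 0.36) rose as in E1-KO, and Msx1 fell by 5.05. The edgeR count was 5919 genes (2808 higher, 3111 lower), 2192 of them by at least 1 on the log2 scale. It was 2535 with the 6 libraries of both genotypes alone and 8887 without WT replicate 2.

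In D-KO the HoxB list lay lowest against WT (median -6.01, adjusted p = 2.50e-27), with Hoxb4 at -7.11 ± 0.71 (adjusted p = 2.89e-07), Hoxb2 at -5.87 ± 0.55, Hoxb8 at -6.83 ± 1.08, Hoxb1 at -5.40 ± 0.47 and Hoxb9 at -3.02 ± 0.30. Hoxb7 had 3 counts in D-KO against 160 in WT (log2 ratio of totals -5.66, counting interval -7.96 to -4.09). HoxB non-coding RNAs fell in 2 of 3 cases (median -6.57, or -5.35 with Hoxb5os, which had 0 counts, at its bound; adjusted p = 1.75e-05). HoxA genes fell in 8 of 11 cases (median -1.13, adjusted p = 1.05e-07), with Hoxa7 at -1.99 ± 0.14, with Hoxc4 of the HoxC cluster at -1.47, -1.48 and -3.50 in the 3 KO genotypes, a fall in each. Hoxc13, the other HoxC gene tested, did not pass in any, and Hoxd13, the single HoxD gene tested, fell by 1.48, 2.38 and 1.92. Its call in E1-KO was lost without WT replicate 1 or without any of the E1-KO libraries (log2 fold changes -1.75 to -1.30), and in D-KO without D-KO replicate 1 or 3 (-1.86 and -1.79). Primitive endoderm genes fell in 13 and rose in 2 of 21 cases (median -0.79, adjusted p = 0.000251), with Gata4 at -1.42 ± 0.21. Naive pluripotency genes rose in 7 and fell in 1 of 18 cases (median 0.26, adjusted p = 0.00442; adjusted p = 0.0535 with an estimated correlation). General pluripotency genes rose in 7 of 13 with none lower (median 0.55, adjusted p = 0.000818), with Tdgf1, a Nodal co-receptor, at 0.82 ± 0.10 and Utf1 at 1.48 ± 0.25. Retinoic acid response genes fell in 11 and rose in 3 of 24 cases (median -0.51, adjusted p = 0.0440), with Cyp26a1, which degrades retinoic acid, at -1.19 ± 0.18. The call was lost with an estimated correlation (adjusted p = 0.473) and without WT replicate 1, WT replicate 2 or D-KO replicate 1 (medians -0.55, -0.22 and -0.58). Of the 2-cell-like genes 13 of 14 fell (median -1.95, adjusted p = 4.24e-11; adjusted p = 0.0535 with an estimated correlation). FGF and ERK response genes rose in 4 of 16 cases (median 0.31, adjusted p = 0.0189; adjusted p = 0.153 with an estimated correlation, and lost without WT replicate 1, median 0.37), with Myc at 0.90 ± 0.15. All 4 Y-linked genes tested fell.

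Formative and primed epiblast genes did not move together in D-KO (2 rose, 3 fell, median 0.01, adjusted p = 0.908), with Dnmt3b at 0.99 ± 0.10 and Sall2 at -1.17 ± 0.15. Nor did genes flanking HoxB (2 rose, 3 fell), early neural (2 rose, 3 fell), primitive streak and mesoderm (2 rose, 2 fell), trophectoderm (3 rose, 1 fell), fibroblast (2 fell), germline (2 rose, 2 fell), proliferation (5 rose), p53 targets (3 rose, 6 fell), amino acid and ER stress (3 rose), Nodal signalling (2 rose, 4 fell), Wnt response (1 rose, 2 fell) and imprinted genes (4 rose, 7 fell). Of these, germline and stress genes passed without WT replicate 2 (medians -0.43 and 0.53) and imprinted genes without WT replicate 3 (median 0.06). None of 12 mitochondrially encoded genes passed in edgeR (median -0.58, adjusted p = 0.254), whereas the list passed without WT replicate 2 (median -0.91) and turned to a rise without WT replicates 1 and 3 (median 0.42). That fit has 1 WT library, so the WT spread is not measured in it. Medians, means and test directions differed in sign for general pluripotency in E1-KO (median -0.17, mean 0.12), fibroblast (-0.10 and 0.10 in E1-KO, -0.10 and 0.22 in E2-KO) and germline in E1-KO (-0.05 and 0.18), and in D-KO for Nodal signalling (0.11 and -0.38), proliferation (-0.07 and 0.05), trophectoderm (0.23 and -0.04, tested upward) and formative and primed epiblast (0.01 and -0.07, tested upward). They also did between E1-KO and E2-KO for primitive streak and mesoderm (-0.10 and 0.09), early neural (-0.15 and 0.04), trophectoderm (-0.05 and 0.03), 2-cell-like (0.05 and -0.15) and imprinted genes (0.01 and 0.04, tested downward). The same held for HoxA between D-KO and E2-KO (0.01 and -0.04) and HoxB non-coding RNAs in the interaction (0.16 and 0.30, tested downward). None of these lists passed where its signs differed. Adjusted over the list alone, counts changed in E1-KO for formative and primed epiblast (9 fell), trophectoderm (1 fell), 2-cell-like (14 fell), flanking (6 fell), proliferation (10 fell) and FGF and ERK genes (5 rose). In E2-KO they changed for HoxA (9 fell), formative (8 fell), primitive endoderm (4 rose), trophectoderm (1 fell), proliferation (2 rose), p53 targets (6 rose), Nodal (3 rose) and mitochondrial genes (11 fell). In D-KO they changed for HoxA (9 fell), retinoic acid response (5 rose), general pluripotency (8 rose), primitive endoderm (3 rose, 14 fell), early neural (4 fell), trophectoderm (2 fell), fibroblast (1 rose, 3 fell), germline (3 rose, 5 fell), p53 targets (7 fell), Nodal (3 rose) and imprinted genes (8 fell). Csmd3 had 1099 counts in D-KO, at least 385-fold above the WT floor. Egr4 (log2 ratio of totals 6.28, counting interval 4.40 to 9.34), Spint5, Cyp2b23 (4.74 ± 0.15), H2-Eb1 (3.71 ± 0.36) and the thromboxane receptor gene Tbxa2r (3.70 ± 0.62) rose most after it. Spint5, called in all 3 genotypes at 5.05 ± 1.16, 4.55 ± 1.17 and 5.49 ± 1.16, did not pass in any of them without WT replicates 1 and 3. The edgeR count was 3824 genes (1777 higher, 2047 lower), 1477 of them by at least 1 on the log2 scale. It was 1438 with the 6 libraries of both genotypes alone, 7006 without WT replicate 2, 2413, 2454 and 2484 without D-KO replicates 1, 2 and 3, and 6238 without WT replicates 1 and 3.

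**Figure D2:**
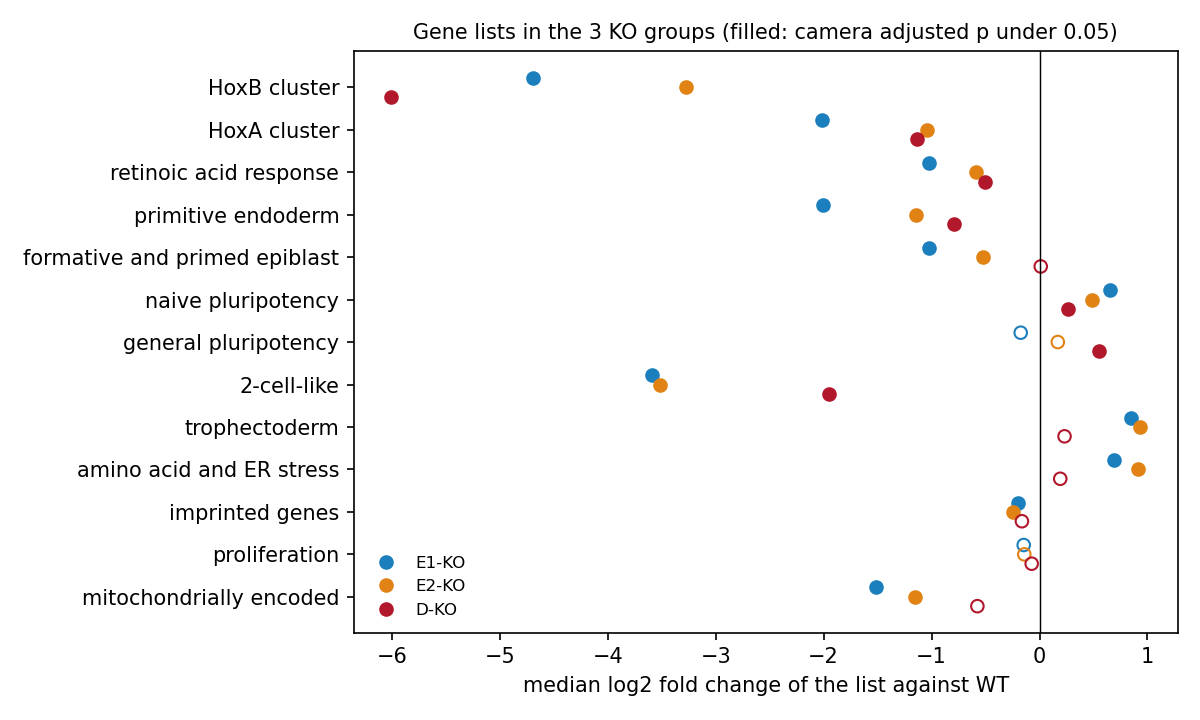
Median log2 fold change against WT of 13 of the 26 gene lists (rows) in E1-KO, E2-KO and D-KO, 3 libraries per genotype; filled points passed camera at an adjusted p below 0.05. HoxB medians were -4.69, -3.28 and -6.01, and those of primitive endoderm genes -2.01, -1.14 and -0.79. The mitochondrial D-KO median, -0.58, became 0.42 without WT replicates 1 and 3.

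As a list, HoxB genes were lower in D-KO than in either single deletion, and several differentiation lists lay nearer to WT in D-KO than in E1-KO. This position was not particular to those lists. On the main axis of variation over all tested genes (first principal component, 45.4% of variance) D-KO also lay between WT and both single deletions. Its libraries stood at 1.33 to 5.82, WT at -106 to -34.9, E1-KO at 33.0 to 35.8 and E2-KO at 29.7 to 37.1. Against E1-KO, 4 HoxB genes fell: Hoxb4 (-2.77 ± 0.75, adjusted p = 0.00916), Hoxb9 (-1.42 ± 0.32), Hoxb5, at least 3.85-fold lower, and Hoxb7, with 3 counts against 20 (log2 ratio of totals -2.68, counting interval -5.08 to -0.93). The calls of Hoxb5 and Hoxb7 were lost without any single D-KO library (adjusted p = 0.0619 to 0.119). Hoxb5 also lost it without E1-KO replicate 3, and Hoxb7 without E1-KO replicate 1, E1-KO replicate 2 or E2-KO replicate 2. Against E2-KO, Hoxb2 (-2.11 ± 0.59), Hoxb3 (-3.38 ± 1.09), Hoxb4 (-4.21 ± 0.73) and Hoxb5 (at least 9.86-fold lower) fell. Hoxb2 and Hoxb3 lost their calls in most fits without 1 library. Hoxb1 did not differ between D-KO and E1-KO (0.85 ± 0.70, adjusted p = 0.411) or E2-KO (-0.66 ± 0.57, adjusted p = 0.517). The HoxB list fell against E1-KO (median -1.86, or -1.39 with genes at 0 counts at their bound, adjusted p = 0.00803; adjusted p = 0.138 with an estimated correlation) and E2-KO (median -2.30, or -1.98 at the bounds, adjusted p = 1.82e-08). Without WT replicates 1 and 3, whose spread enters every comparison here, 6 HoxB genes fell against E1-KO and 8 against E2-KO; limma-voom with all libraries called 1 and 2. Against E1-KO, primitive endoderm genes rose in 11 of 21 cases with none lower (median 0.83, adjusted p = 3.53e-10; Cubn 3.11 ± 0.32), as did formative and primed epiblast genes in 10 of 12 (median 0.99, adjusted p = 1.60e-08). Also higher were retinoic acid response genes in 12 of 24 with 1 lower (median 0.58, adjusted p = 2.17e-05; adjusted p = 0.0778 with an estimated correlation) and Nodal signalling genes in 7 of 9 with 1 lower (median 0.59, adjusted p = 0.000152). Naive pluripotency genes fell in 10 of 18 and rose in 2 (median -0.40, adjusted p = 0.00695; adjusted p = 0.0778 with an estimated correlation). Trophectoderm genes fell in 5 of 12 (median -0.68, adjusted p = 0.000140), while general pluripotency (6 of 13, median 0.35) and proliferation genes (3 of 21, median 0.22) rose. Mitochondrially encoded genes (7 of 12, median 1.03, adjusted p = 5.19e-06; 0.168 with an estimated correlation) and 2-cell-like genes (8 of 14, median 1.49, adjusted p = 2.98e-08; 0.0778) were higher too. HoxA (median 0.57), imprinted (0.14), flanking (-0.21), germline (-0.38), p53 target (-0.23) and stress response lists (-0.63) also passed, but not with an estimated correlation. Of these, germline genes lost the call without E1-KO replicate 2 (median -0.41). Imprinted genes lost it without WT replicate 1, D-KO replicate 2 or any E1-KO or E2-KO library (medians 0.11 to 0.24). Against E2-KO, formative and primed epiblast genes rose in 4 of 12 cases (median 0.66, adjusted p = 2.30e-07) and 2-cell-like genes in 7 of 14 (median 1.62, adjusted p = 2.37e-12). Stress response genes fell in 7 of 15 and rose in 1 (median -0.74, adjusted p = 8.55e-11). Primitive endoderm (median 0.04, adjusted p = 0.415) and naive genes (median -0.22, adjusted p = 0.117) did not pass against E2-KO in camera. Retinoic acid response genes passed as higher (3 of 24 rose, 1 fell; median 0.17, adjusted p = 0.0423), but not with an estimated correlation (adjusted p = 0.322), nor without WT replicate 1, WT replicate 2, E2-KO replicate 1 or D-KO replicate 2 (medians 0.17, 0.17, 0.14 and 0.20). Naive genes passed without WT replicate 3 (median -0.22). Trophectoderm genes fell in 4 of 12 (median -0.56, adjusted p = 8.32e-06), and the proliferation list (median 0.16, no gene called) passed as higher. Mitochondrially encoded (median 0.63), general pluripotency (0.13), Nodal signalling (0.21), p53 target (-0.15), flanking (-0.16) and HoxB non-coding lists (-3.37) passed, but not with an estimated correlation. The flanking list also lost the call without WT replicate 1 or 3, E1-KO replicate 1, D-KO replicate 2 or any E2-KO library (medians -0.15 to -0.12).

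Among single genes, D-KO exceeded E1-KO most in Csmd3, Grm6 (3.28 ± 0.61), the casein gene Csn3 (3.28 ± 0.55) and Aoc3 (3.05 ± 0.33). D-KO lay below E1-KO in H19, a member of the imprinted list, Platr15 (-2.86 ± 0.34) and Trim66 (-2.83 ± 0.34). It exceeded E2-KO in Usp17la, a member of the 2-cell-like list (2.29 ± 0.37), and lay below E2-KO in Loxl4 (-2.33 ± 0.33). Between E1-KO and E2-KO no HoxB gene passed in edgeR. DESeq2 called 2, and 5 passed without WT replicates 1 and 3. The HoxB list was lower in E1-KO (median -0.80, adjusted p = 0.00414; adjusted p = 0.127 with an estimated correlation), as were primitive endoderm genes, 4 of 21 called (14 of 21 adjusted over the list alone; median -0.80, adjusted p = 1.77e-22). HoxA (median -0.45), retinoic acid response (-0.38), naive (0.10), general pluripotency (-0.21), formative (-0.15), germline (0.22), stress response (-0.26), Nodal signalling (-0.31) and mitochondrially encoded lists (-0.37) passed between them, but not with an estimated correlation. Naive and germline genes also lost the call without E1-KO replicate 2 (medians 0.09 and 0.18) or E2-KO replicate 1 (0.10 and 0.24), and mitochondrial genes without E1-KO replicate 1 or E2-KO replicate 2 (-0.28 and -0.25). Efhc2 was higher in E1-KO by 2.36 ± 0.22, as was H19 by 2.93 ± 0.42 (adjusted p = 0.0568 without E2-KO replicate 3), and Csmd3 was at least 213-fold lower. The edgeR counts were 2674 genes for D-KO against E1-KO (1414 higher, 1260 lower), 751 for D-KO against E2-KO (309 higher, 442 lower) and 100 between E1-KO and E2-KO (54 higher, 46 lower). These counts turned on the WT libraries in the shared spread: with the 9 KO libraries alone they were 7898, 6124 and 3467. Left-out libraries moved them too, to 4934 and 4902 (without WT replicates 2 and 3), 1174, 1314 and 1279 (E1-KO replicates 1, 2 and 3) and 1433, 1244 and 1207 (D-KO replicates 1, 2 and 3) for D-KO against E1-KO. For D-KO against E2-KO they were 1354, 2875 and 2468 (WT replicates 1, 2 and 3), 232, 233 and 304 (E2-KO) and 245, 277 and 227 (D-KO). Between E1-KO and E2-KO they were 199, 558 and 722 (WT), 16, 28 and 25 (E1-KO), 22, 28 and 23 (E2-KO) and 66, 55 and 59 (D-KO). With library totals as the only scaling, 35.9% of the calls between D-KO and E1-KO were rises instead of 52.9%, and 65% instead of 54% between E1-KO and E2-KO. With GC content and length trends removed, 51.7% instead of 41.1% were rises between D-KO and E2-KO.

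Because the series title speaks of synergy, the D-KO change was tested against the sum of both single changes on the log2 scale. No HoxB gene was called as falling by more than that sum in edgeR, but for most of them a larger fall could not have been seen. Hoxb1 and Hoxb2 fell by less, with interactions of 5.60 ± 0.82 (adjusted p = 0.000178) and 2.79 ± 0.74 (adjusted p = 0.0141), the latter lost without D-KO replicate 2 (2.55). Hoxb4 lay at the sum within its error (0.13 ± 0.81, adjusted p = 0.964). The number of HoxB genes called above the sum was 1 in limma-voom, 4 in DESeq2 and 5 without WT replicate 3. The HoxB list did not pass (median 0.65, adjusted p = 0.148). Hoxb5 and Hoxb6 cannot be judged, since a count of 0 sets only a bound on their fall. For Hoxb1, Hoxb2, Hoxb3, Hoxb7 and Hoxb8 the sum itself lies below the D-KO floor of 0.0998 CPM. A fall beyond the sum could therefore have shown only in Hoxb4, Hoxb9 and Hoxb13, and none of these was called. Hoxb4 had only 6 counts in D-KO, and 38% of simulated interactions of 1 on the log2 scale were recovered. A moderate fall beyond the sum is thus not excluded for these genes, and the test leaves synergy undecided for the others. On the linear CPM scale the sum of the single losses exceeded the WT level, as Hoxb4 shows: 29.1 CPM in WT, 1.43 in E1-KO and 3.92 in E2-KO. An expectation additive in CPM then lies below 0 for 9 HoxB genes, so D-KO could only lie above it and the test on that scale is not informative. Over all genes, 5909 departed from the log2 sum (3040 above, 2869 below; 3354 by at least 1). With library totals as the only scaling, which shifted the median of all genes by -0.17, 38.7% of these lay above instead of 51.4%. For genes shared by all KO genotypes the sum counts the common change once too often: Egr4, with 2 counts in WT, rose in all 3 and had a fitted interaction of -5.39, for which no counting interval was computed.

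The 3 comparisons with WT called many genes in the same direction. E1-KO and E2-KO shared 4334 calls (2073 higher, 2261 lower), against 441 and 576 for independent lists of these sizes. The mean was 8.55 for simulated unchanged groups, which shared WT libraries that were simulated too. Genes were drawn independently there, so trends across genes in the real WT libraries, such as those with GC content, were not reproduced. E1-KO and D-KO shared 2423 (279 and 379 for independent lists, 11.1 simulated) and E2-KO and D-KO 2912 (298 and 380, 8.20 simulated). Correlations of the log2 fold changes across genes, which are not independent replicates, were 0.884, 0.721 and 0.809, against a simulated mean of 0.791, 0.792 and 0.789 with no effect. Covariances were 0.676, 0.484 and 0.532, against 0.100 simulated for each. With 3 WT libraries the controls cannot be split into parts of at least 2, so part of the excess may come from the shared controls. In all 3 comparisons 2305 genes changed in the same direction (1095 higher, 1210 lower), 60.3% of the D-KO calls. Without WT replicate 2 the pairs shared 7403, 5363 and 5935 calls.

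Some differences from WT followed chromosome segments in every KO genotype. With GC content and length trends removed, the 205 expressed genes of chromosome 6 between 110 and 150 Mb lay lower than in WT, at medians of -0.54 (E1-KO), -0.54 (E2-KO) and -0.58 (D-KO), with 129, 138 and 137 called lower, while D-KO and E1-KO differed there by -0.06. Nanog (122707489) and Tead4 (128227143) lie in this segment and the HoxA cluster outside it. The 73 genes of chromosome 10 between 50 and 70 Mb lay higher by 0.72, 0.70 and 0.67, and the 129 genes of chromosome 2 between 160 and 180 Mb by 0.48, 0.41 and 0.44. Of the list members, Cdk1, Ddit4 and Nodal lie in the former, and Aurka, Cebpb, Hnf4a, Sall4, Snai1 and Tfap2c in the latter; the lists, among them stress response (Ddit4, Cebpb) and trophectoderm (Tead4, Tfap2c), were not tested without them. These segments were chosen after the values were seen, and held 4.51% (E1-KO), 4.53% (E2-KO) and 6.33% (D-KO) of the genes called. Of their 407 expressed genes, 259, 268 and 242 were called. Among all 16765 tested genes, which include genes expressed at lower levels, 34.2%, 35.3% and 22.8% were called. The Y-linked genes, of which Ddx3y, Eif2s3y, Usp9y and Uty were tested, together had 1218, 1092 and 1071 counts in the WT libraries and 1 count in the 9 KO libraries. Ddx3y was at least 551-fold, 520-fold and 530-fold lower than in WT in the KO genotypes, in the same order.

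**Figure D3:**
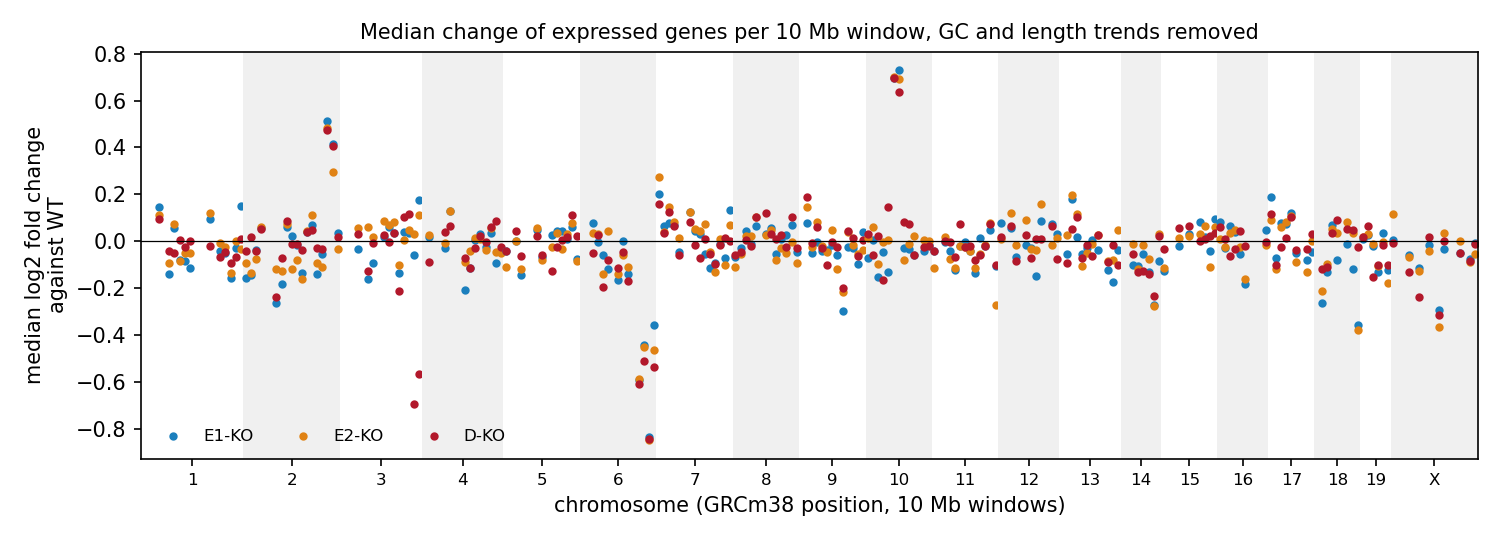
Median log2 fold change against WT of expressed genes in 10 Mb windows along the genome (x axis, chromosomes 1 to 19 and X; windows with at least 20 genes), for E1-KO, E2-KO and D-KO with trends in GC content and length removed. Windows on chromosome 6 beyond 110 Mb lie low and those on chromosome 10 between 50 and 70 Mb high in all 3 genotypes, and the end of chromosome 3 lies low in D-KO (median -0.58 over 46 genes).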

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

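Every result in the next paragraph was picked out because the D-KO change differed from the sum of both single changes in a test of that difference (the interaction in edgeR). The patterns weighed after it also take in comparisons with WT and between KO genotypes. The tests of GC content, of sample splits and of the shared difference were written before their results were seen; those of a stock difference and of the HoxB level were written after.

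The interaction had 5909 genes. On the log2 scale Hoxb1 stood at 5.60 and Hoxb2 at 2.79. Outside HoxB, genes with large values above the sum were Msx1 at 6.95, Zscan4e at 5.79, Zscan4b at 5.79 and Zscan4-ps3 at 5.65. The largest below it were Loxl4 at -7.13, Slc13a5 at -5.90, Egr4 at -5.39 (2 counts in WT), Efhc2 at -5.35 and H2-Eb1 at -4.89. Lists above the sum, by their medians, were HoxA (1.80), retinoic acid response (1.13; adjusted p = 0.0597 with an estimated correlation), formative and primed epiblast (1.41), primitive endoderm (2.13), 2-cell-like (5.14), proliferation (0.29; adjusted p = 0.0664 with an estimated correlation), Nodal signalling (0.80), imprinted (0.25) and mitochondrially encoded genes (2.18; adjusted p = 0.205 with an estimated correlation). Lists below it were naive pluripotency (-0.85), trophectoderm (-1.86) and stress response genes (-1.29).

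The first pattern weighed is that many genes differ between each KO genotype and WT. GC content and gene length bias of single libraries is argued against as the whole cause, since the lowest ratio of corrected to uncorrected counts was 0.889, although only 4016 of 5739 (E1-KO), 3732 of 5919 (E2-KO) and 3109 of 3824 (D-KO) calls were kept. A difference between the WT and KO cell stocks that the deletions did not make was weighed next. Y-linked genes had 1218, 1092 and 1071 counts in the WT libraries, 1 in E1-KO replicate 2 and 0 in every other KO library. On chromosome 6 between 110 and 150 Mb, chosen after its values were seen, GC-corrected medians were -0.54 (E1-KO), -0.54 (E2-KO) and -0.58 (D-KO). In the window with the largest shared fall, the KO genotype that changed least had a median of -0.850. Values so alike in all KO genotypes are what a stock difference would give. Falls of the same 9 HoxB genes were shared by all KO genotypes too, so likeness alone does not argue against the deletions. For these genes and for the other calls, such a stock difference cannot be told from the deletions by this design. In splits of the 6 libraries compared, 1 of 10, the true one, reached the observed count in each of the 3 comparisons with WT, and the highest other had 1, 0 and 0 genes. With 10 splits the share cannot go under 0.1, so that this count cannot decide; the same held for D-KO against E1-KO, D-KO against E2-KO and E1-KO against E2-KO (1 of 10 each).

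The second is that many genes depart from the sum of the single changes. GC content and gene length are argued against as the whole cause, with a ratio of corrected to uncorrected counts of 0.929, although only 4058 of 5909 calls were kept. A shared difference of all KO genotypes from WT, counted once per genotype by the sum, remains open. For 0.648 of these genes D-KO differed from neither single KO, which met the prediction written before for this explanation. With the 9 KO libraries alone, a fit chosen after the results were seen, that share was 0.185. The mean of both single changes, with its sign reversed, had a median ratio to the interaction of 0.635 (quartiles 0.509 and 0.771). The interaction contains both single changes by construction, so this ratio is large even for a gene unchanged in D-KO. It therefore does not measure a shared difference. Of 30 splits only the true 1 reached 5909 genes and the highest other had 90. The other splits mixed genotypes within groups, which widens the spread and lowers the count in advance. This count therefore cannot decide on an accidental grouping of libraries.

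The third is that primitive endoderm, retinoic acid response, formative and naive lists lie nearer to WT in D-KO than in E1-KO, although HoxB is lowest in D-KO. Over all tested genes, D-KO likewise lay between WT and E1-KO on the first principal component. GC content and length are argued against as the whole cause, since 4 of 4 lists kept their call and direction between D-KO and E1-KO after the correction. With an estimated correlation, retinoic acid response and naive genes (adjusted p = 0.0778 each) and the HoxB list (adjusted p = 0.138) no longer passed in camera. Between E2-KO and D-KO the formative list did not follow the HoxB level. It was higher in D-KO (median 0.66, camera adjusted p = 0.00978 with an estimated correlation), where HoxB was lower (median -2.30, adjusted p = 0.0201). This check used the same D-KO libraries that led to the choice of the list, so it is not independent of that choice. A difference of the D-KO cells unrelated to HoxB could also give it, so the cause stays undecided. Whether the primitive endoderm, retinoic acid response and naive lists follow the HoxB level stays open, with 0 of 3 nearer to WT in D-KO than in E2-KO in both camera tests. No other biological explanation was tested.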

How the results depend on the processing

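Removal of GC content and length trends, sample quality weights, the 9 KO libraries alone and the fit without WT replicates 1 and 3 were chosen after the results were seen. The 9 HoxB falls in each comparison with WT kept their calls in each setting in which these genes were tested again, which leaves out the 6-library fits and the fold minimum, whereas the numbers of genes moved. Causes were not tested except where fewer libraries or a stricter rule give them.

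With only the 6 libraries compared, counts were 2552 (E1-KO against WT), 2535 (E2-KO against WT), 1438 (D-KO against WT), 8025 (D-KO against E1-KO), 5872 (D-KO against E2-KO) and 3377 (E1-KO against E2-KO). With the 9 KO libraries the last 3 were 7898, 6124 and 3467. Without WT replicates 1 and 3 they were 8030, 6158 and 3457, and D-KO against WT had 6238. With limma-voom quality weights they were 7975, 5790 and 2868. D-KO against E2-KO and E1-KO against E2-KO had 1506 and 259 with GC content and length trends removed, 1166 and 249 in DESeq2, and 1472 and 415 without a filter. A log2 fold change of at least 1 left 2149, 2192, 1477, 857, 267, 54 and, for the interaction, 3354. At an adjusted p below 0.01, overlaps were 2315 (E1-KO and E2-KO), 1226 (E1-KO and D-KO) and 1415 (E2-KO and D-KO).

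The HoxB list fell short of the threshold for D-KO against E1-KO with quality weights (-1.73), without WT replicates 1 and 3 (-1.87) and with an estimated correlation (-1.86). For E1-KO against E2-KO it did so in limma-voom (-0.90), with quality weights (-0.85), with an estimated correlation (-0.80) and without its largest member (-0.46). The interaction list passed with quality weights (1.47) and in fry (0.65). Without WT replicates 1 and 3 the mitochondrial list for D-KO against WT turned to 0.42 and mt-Nd5 to 0.43, with a single WT library whose spread is assumed to be that of the other groups.

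Leaving out 1 library in turn gave 3965 to 8753 (E1-KO against WT), 3969 to 8887 (E2-KO), 2413 to 7006 (D-KO), 1174 to 4934 (D-KO against E1-KO), 227 to 2875 (D-KO against E2-KO), 16 to 722 (E1-KO against E2-KO) and 4621 to 8673 (interaction). Overlaps were 3192 to 7403, 1672 to 5363 and 1948 to 5935. HoxB medians were -4.95 to -4.21, -3.45 to -3.20, -6.35 to -5.61, -1.98 to -1.52, -2.67 to -2.17, -0.97 to -0.61 and 0.47 to 1.00, in the order of the comparisons above. Of 2016 list values 1954 stayed on their side of the threshold, 33 weakened and 29 strengthened; of 4032 values of named genes these were 3876, 131 and 25.

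With the replicate number as a replicate block the counts were 5414, 5582, 3467, 2310, 581, 71 and 5609, and 168 of 168 list results and 334 of 336 named-gene results kept their call. Hoxb7 lost it between D-KO and E1-KO (-2.49), leaving 3 HoxB genes there, and Hoxd13 in E1-KO against WT (-1.47). Correlations between deviations of same-number libraries ran from -0.175 to 0.139, and 3 of 12 libraries correlated best with their own number. Depth limits genes near 0.0949 to 0.102 CPM.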

Other observations

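Segments and genes in this part were chosen after their values were seen. On chromosome 3 between 140 and 160 Mb, 46 expressed genes lay lower in D-KO alone, with a median log2 fold change of -0.58 against WT (44 of 46 lower, 33 called lower) once GC content and length trends were removed. E1-KO and E2-KO stood at -0.01 and 0.09 there, and D-KO at -0.61 and -0.60 against them. Per library the median relative log2 CPM was -0.47, -0.45 and -0.39 in D-KO and 0.05 to 0.41 in the others.

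Csmd3 had 0 counts in WT and E1-KO, and 20.5 ± 1.84 CPM in E2-KO and 36.6 ± 2.24 in D-KO (SD, n = 3). Efhc2, on chromosome X, stood at 0.735 CPM in WT, 35.3 in E1-KO, 6.86 in E2-KO and 7.27 in D-KO. Among germline genes Dazl, an RNA-binding protein gene, went from 101 CPM in WT to 29.9, 23.0 and 19.5 in the KO genotypes, and Tex101 from 1.57 to 9.14, 8.45 and 9.51. Of the genes beside HoxB, Calcoco2 had 355 CPM in WT against 204, 192 and 188. After removal of GC content and length trends, of 204 windows of 10 Mb, 6 moved by more than 0.4 on the log2 scale in all 3 KO genotypes, 3 lower and 3 higher.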
